A study of Rattus norvegicus with 21 samples.

How the data were processed

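DNA methylation was measured by bisulfite sequencing of dorsal striatum from 120-day-old Sprague Dawley rats. Bisulfite treatment turns unmethylated cytosines into bases read as T, so the share of reads that still show C at a CpG is taken here as its methylation level. Different modified forms of cytosine that bisulfite leaves as C were not told apart. Per the labels' protocols, rats of the lesioned groups received 6-hydroxydopamine, a toxin of catecholamine neurons, in the medial forebrain bundle on one side and recovered for 3 weeks. The L-DOPA group then had daily injections of 6 mg/kg for 7 days, and tissue was taken 3 h after the last one. Of the 21 samples, 6 are unlesioned and saline-treated, 8 are lesioned and saline-treated and 7 are lesioned and L-DOPA-treated. The labels number the samples within each group but do not name the animal behind each, so p-values measure the spread between these samples.

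Per the labels' protocols and the series' design text, genomic DNA was bisulfite-converted and sequenced as single-end reads of 50 bases, and reads were trimmed, mapped to rn5, sorted, de-duplicated and passed to methylKit. The submitters called differences at a p corrected by a sliding linear model, after scaling coverage between samples. The submitters' processing notes name FastQC 0.10.1, Trim Galore 0.3.7, Bismark 0.13.0, SAMtools 0.1.19 and methylKit 0.9.2. The deposited files list one cytosine of a CpG per line with its strand, its coverage as a count of reads, and the percent of those reads with C and with T, as the authors computed them. The percent and the coverage gave whole methylated read counts for 100% of the cytosines in every library. Every listed cytosine had at least 10 reads. Coverage was not scaled to a common depth in the main test. Positional de-duplication of 50-base reads would leave at most about 50 reads per strand over a cytosine, yet 36.4% to 58.8% of the cytosines of a library had more than 50 reads. Duplicates made by PCR may therefore still be counted, and counting errors would then be too small.

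Libraries held 978694 to 1291334 CpGs. Total coverage summed over cytosines was 5.96e+07 to 1.64e+08 reads per library, where one read can count at several CpGs. Median coverage per cytosine was 37 to 70 reads. Over the tested tiles, the median was 125 to 288 reads per tile and library, summed over CpGs in the same way. Library numbers in the deposited names fall into 2 separate runs, called series 1 and series 2 here. Series 1 holds lesioned saline replicates 1 to 6 and L-DOPA replicates 1 to 3. Series 2 holds the other 12 libraries, among them all 6 unlesioned ones, so the unlesioned group has no library in series 1. What the 2 runs stand for is not given in the sources used here.

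The genome was divided into tiles of 250 bp, after the series' design text. A tile's methylated and unmethylated counts in a library were summed over its CpGs with at least 10 reads, and a tile with fewer than 2 such CpGs in a library was left out there. Of 515917 tiles seen in any library, 184765 were measured in at least 5 libraries of every group. Leaving out tiles with pooled methylation under 1% or over 99% left 180953 tested tiles, and 139031 of these were measured in all 21 libraries. The main test was a quasi-binomial logistic model fitted to the counts of all 21 libraries with 3 groups. Its dispersion was moderated across tiles with the method of limma's squeezeVar and kept at 1 or above, the contrast was tested with an F-test on the deviance, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Differences are given in percentage points between unweighted group means. The median dispersion was 3.28, where 1 means binomial counting error alone.

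Mean methylation was the unweighted mean over the 139031 common tiles, compared with exact two-sided permutation tests adjusted over 3 comparisons. To relate the effects of lesion and of L-DOPA, differences per tile were correlated with the 8 lesioned saline libraries split into 2 sets of equal size in all 70 ways, so that no library entered both effects. Tiles were named by a rule fixed before the data were examined: the 10 with the largest difference per direction among those past the threshold, or, where fewer than 3 passed, the 5 with the smallest p in that direction, given as values that did not pass. Parts of the rule that name promoters were dropped without an rn5 annotation. The CpG number of a tile counts the CpGs listed in any library, not those of the genome sequence, and tiles with many are called CpG-dense. The read ratio of a library is its median reads per tile of 15 or more CpGs over its median reads per tile of 2 or 3 CpGs. Libraries were compared in all 210 pairs, at common tiles of neither very low nor very high methylation pooled over the pair. The mean squared difference was 2.86 to 32.5 times that of binomial counting with reads taken as independent, which remaining PCR duplicates would not be.

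The test was tried on simulated data with the real tiles' levels, coverage and dispersion, in which 200 of 180953 tiles were changed, 50 for each size. Each tile and library was drawn independently, so shifts shared by many tiles of a library were not simulated. Rates in the real libraries may therefore differ from the simulated ones. Of changes of 20 points, 40% were recovered for L-DOPA against lesioned saline, 36% for lesioned against unlesioned saline and 48% for L-DOPA against unlesioned saline. Of changes of 15 points, 20%, 18% and 22% were recovered in the same order, of changes of 10 points 0%, 2% and 2%, and of changes of 5 points 0% in each. All changed tiles had intermediate methylation, so these rates do not cover tiles of low or high methylation. Wrong calls numbered 3, 1 and 10, and 5.49%, 5.97% and 6.63% of the unchanged tiles had an unadjusted p under 0.05. For L-DOPA against unlesioned saline, the 10 stood beside 24 right calls at 20 points, 11 at 15 and 1 at 10. For L-DOPA against lesioned saline, the 3 stood beside 20 right calls at 20 points and 10 at 15. In both, wrong calls exceeded the share that a threshold of 0.05 allows, so adjusted p-values there may be too small. The logistic model without overdispersion made 17938, 19547 and 21737 wrong calls at an adjusted p under 0.01 on the same data.

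Alternatives set before the data were examined were that model with an adjusted p under 0.01, with and without a minimum difference of 5 points, limma on log2 odds, stricter thresholds, at least 20 reads per CpG, removal of CpGs above the 99.9th percentile of coverage, scaled coverage, tiles or CpGs measured in all 21 libraries, no range filter, 1000 bp tiles, a fit of 2 groups alone, autosomes alone, library series as a term, each series alone, a replicate block, and each library left out. The model without overdispersion here uses the Benjamini-Hochberg method and unscaled counts, so it is near to but not the same as the submitters' test. Added after the data were seen were the classes of tiles, the removal of 3 libraries with concentrated reads, and the read ratio as a term with and without library series. Gene names, promoters, genomic context and the 14 gene lists fixed beforehand were not used here, because the gene table at hand is of another build than rn5. Computations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.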

Results

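The data comprised 21 bisulfite libraries of rat dorsal striatum, the input area of the basal ganglia that receives dopamine fibres from the midbrain. The 6-hydroxydopamine lesion destroys those fibres on one side, and L-DOPA, the precursor of dopamine, induces abnormal movements (dyskinesia) when given daily to such animals. The comparisons ask how DNA methylation differs with the lesion, with L-DOPA after the lesion, and with both. The labels do not say whether the unlesioned samples come from separate animals, from sham-operated ones or from the other hemisphere of lesioned animals, which leaves open what else differs in each comparison with them. Tiles are given by rn5 position. No gene annotation of rn5 was used here, so whether a tile lies in a gene is not stated.

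Methylation in the striatum was lower in tiles with more listed CpGs in all 3 groups. In unlesioned samples, tiles of 2 or 3 CpGs averaged 62.2% ± 2.77 (SD, n = 6), tiles of 4 to 7 CpGs 52.7% ± 2.34, tiles of 8 to 14 CpGs 20.2% ± 0.804 and tiles of 15 or more CpGs 3.56% ± 0.177. Tiles on the X chromosome averaged 36.0% ± 1.17. Of the 180953 tested tiles, 31.9% had pooled methylation under 20%, 31.3% lay between 20% and 80%, and 36.8% were above 80%. CpGs of the mitochondrial genome read as 1.12% to 1.49% methylated over the 21 libraries. Methylation profiles over common tiles correlated between any 2 libraries at r = 0.950 to 0.991 across tiles, which are not independent replicates.

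Mean methylation over the 139031 common tiles was 46.9% ± 2.07 (SD, n = 6) in unlesioned saline, 46.7% ± 0.910 (n = 8) in lesioned saline and 45.9% ± 2.24 (n = 7) in lesioned L-DOPA rats. L-DOPA differed from lesioned saline by −0.736 points (SE 0.904, exact permutation p = 0.403, adjusted 0.649). Lesioned saline differed from unlesioned saline by −0.183 points (SE 0.902, exact permutation p = 0.838, adjusted 0.838), and L-DOPA from unlesioned saline by −0.919 points (SE 1.19, exact permutation p = 0.433, adjusted 0.649). All 3 differences were smaller than the spread between libraries. None of 8 classes of tiles, by level, CpG number or the X chromosome and chosen after the data were seen, passed in any comparison (smallest of 24 adjusted exact permutation p = 0.952). Within series 1, L-DOPA differed from lesioned saline by −0.494 points, and within series 2 by −1.26 points. Within series 2, lesioned differed from unlesioned saline by 0.275 points and L-DOPA from unlesioned saline by −0.986 points.

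The lowest means belonged to 3 libraries whose reads were concentrated in CpG-dense tiles. L-DOPA replicates 3 and 7 averaged 43.0% and 42.5%, with read ratios of 30.2 and 31.3, and unlesioned replicate 1 averaged 43.1%, with a ratio of 33.6. The other 18 libraries averaged 44.8% to 48.5%, with ratios of 13.7 to 24.7. Without these libraries, a setting added after the data were seen, L-DOPA lay 0.557 points above lesioned saline (adjusted exact permutation p = 0.357). The other differences were then −0.944 points for lesioned against unlesioned saline (adjusted exact permutation p = 0.319) and −0.387 points for L-DOPA against unlesioned saline (adjusted exact permutation p = 0.444).

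**Figure D1:**
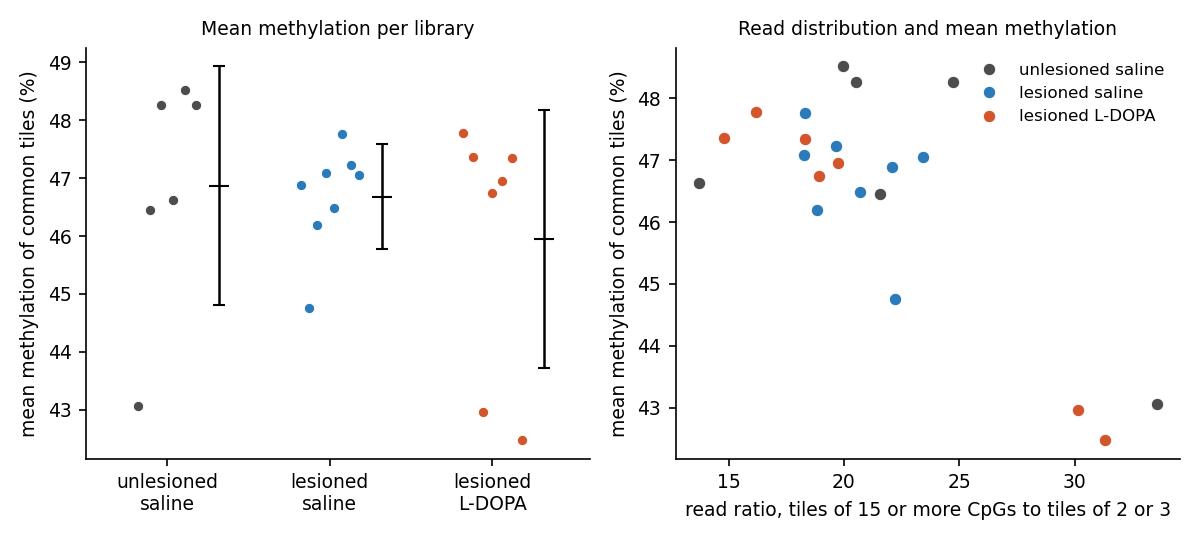
Left, mean methylation (%) of the 139031 common tiles in each library by group, with mean and SD as bars. Right, the same means against each library's read ratio, the median reads per tile of 15 or more CpGs over that of tiles of 2 or 3 CpGs. The 3 libraries with ratios of 30.2 to 33.6 have means of 42.5% to 43.1%, below the other 18.

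L-DOPA against saline in lesioned rats is the comparison named by the study's title. The tile with the smallest p among those lower under L-DOPA, chromosome 7 at 11486251 to 11486500 with 6 CpGs, averaged 24.9% ± 2.80 (SD, n = 7) under L-DOPA and 37.2% ± 5.40 (n = 7) under saline. Each L-DOPA value was at most 29.8%, below each lesioned saline value, and unlesioned samples averaged 31.3% ± 1.74 (n = 6). A further tile on the same chromosome, 12609751 to 12610000 with 8 CpGs, averaged 33.5% ± 5.70 under L-DOPA and 48.8% ± 8.13 under saline, and a tile on chromosome 6 at 154044751 to 154045000 averaged 51.1% ± 12.4 and 70.8% ± 7.92. The other 2 tiles named on this side lay near 0% and differed by −3.25 points (SE 0.790; chromosome 11 at 76763501 to 76763750) and −2.40 points (SE 0.758; chromosome 15 at 63734501 to 63734750). The 5 tiles named on the higher side differed by 7.33 points (SE 1.43; chromosome 4 at 225132501 to 225132750), 6.66 points (SE 1.58; chromosome 7 at 60937751 to 60938000), 3.46 points (SE 0.636; chromosome 4 at 67326751 to 67327000), 2.61 points (SE 0.503; chromosome 13 at 113457501 to 113457750) and 1.07 points (SE 0.222; chromosome 7 at 78244001 to 78244250). None of these tiles passed the test (adjusted p = 1.00 in the quasi-binomial model).

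No tile of 180953 passed between L-DOPA and lesioned saline in the quasi-binomial model, and limma on log2 odds also called 0. At an unadjusted p under 0.05 the model gave 6937 tiles (3.83%, against 5.49% of unchanged tiles in simulated data) and limma 7378. The simulation lacks shifts shared by many tiles of a library. Other splits of the same libraries into groups of these sizes gave a median of 8177 such tiles in the model. The SE of a tile's difference had a median of 2.22 points, and of 4.57 points for tiles of 20% to 80%, and 95% of the differences lay between −8.66 and 5.30 points. The logistic model without overdispersion, near to the submitters' stated test, called 7230 tiles with a change of at least 5 points, of which 6025 were lower under L-DOPA and 1205 higher. Without the 3 libraries with concentrated reads the balance turned: 1266 were lower and 4091 higher. Within series 1 alone (L-DOPA n = 3, saline n = 6), 1 tile passed, on chromosome 12 at 39904751 to 39905000, 32.6 points higher under L-DOPA (adjusted p = 0.000804, quasi-binomial model; not chosen by the rule for named tiles). No tile passed within series 2.

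Lesioned against unlesioned saline compares lesioned and unlesioned samples in the absence of L-DOPA, and 6 of the 8 lesioned but none of the unlesioned libraries belong to series 1. The tile on chromosome 5 at 76371501 to 76371750 had 4 CpGs and a median of 1242 counts per library, summed over these CpGs. It averaged 86.4% ± 2.76 (SD, n = 8) in lesioned and 95.4% ± 2.19 (n = 6) in unlesioned samples, a difference of −9.04 points (SE 1.32). Each lesioned library lay between 82.8% and 90.2% and each unlesioned one between 92.8% and 99.3%. On chromosome 4 at 25541001 to 25541250 (5 CpGs) the means were 84.6% ± 3.72 and 92.1% ± 0.873, on chromosome 20 at 47574501 to 47574750 (5 CpGs) 82.9% ± 3.95 and 90.2% ± 2.21, and on chromosome 3 at 9222001 to 9222250 (5 CpGs) 67.4% ± 9.65 (n = 7) and 92.1% ± 4.75 (n = 5). Among tiles higher after the lesion, chromosome 20 at 6229501 to 6229750 (3 CpGs) averaged 82.4% ± 5.14 (n = 8) against 72.0% ± 3.05 (n = 5). It had the largest difference of the tiles named on this side, and the others differed by 4.00, 2.60, 1.69 and 0.833 points.

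The quasi-binomial model called 0 of the 180953 tiles between lesioned and unlesioned saline, and limma called 0, with 6194 tiles (3.42%, against 5.97% of unchanged tiles in simulated data) and 6718 at an unadjusted p under 0.05. Other splits of the same libraries gave a median of 6836 such tiles in the quasi-binomial model. The chromosome 5 tile passed when only these 2 groups were fitted (adjusted p = 0.0356) and, in settings added after the data were seen, without the 3 libraries with concentrated reads (adjusted p = 0.0399) and with the read ratio as a term (adjusted p = 0.00450), but not with library series as a further term (adjusted p = 0.236). In each of these 3 fits it was the 1 tile called, and over 17 settings other than the main one, these included, its adjusted p ran from 0.00450 to 1. Its difference of group means was −9.55 to −7.72 points in those settings that give percentage points. Added terms such as library series do not adjust that difference. The model without overdispersion called 6050 tiles with at least 5 points, 4301 lower and 1749 higher after the lesion. Without the 3 libraries it called 10744, of which 9653 were lower.

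L-DOPA against unlesioned saline joins both effects and had the smallest p-values. The same chromosome 5 tile averaged 80.6% ± 9.42 (SD, n = 7) under L-DOPA, a difference of −14.8 points (SE 3.67, adjusted p = 0.0940, quasi-binomial model). All 4 of its measured CpGs had lower means in both lesioned groups: at position 76371554, for example, 75.5% ± 8.66 under L-DOPA, 83.0% ± 4.89 under lesioned saline and 93.0% ± 3.01 in unlesioned samples, with at least 129 reads in each library. The chromosome 4 tile averaged 82.0% ± 5.24, a difference of −10.1 points (SE 2.01, adjusted p = 0.103). The tile on chromosome 6 at 154036751 to 154037000 (7 CpGs) averaged 64.8% ± 4.74 under L-DOPA and 73.3% ± 6.12 (n = 8) under lesioned saline, and L-DOPA differed from unlesioned samples by −15.3 points (SE 1.84). A tile on chromosome 7 at 51248501 to 51248750 (3 CpGs) averaged 66.7% ± 12.5 under L-DOPA, 82.3% ± 3.77 under lesioned saline and 91.9% ± 6.05 in unlesioned samples. In the opposite direction, chromosome 8 at 130867251 to 130867500 (6 CpGs) averaged 40.2% ± 5.81 (n = 6) under L-DOPA and 18.3% ± 2.68 (n = 6) in unlesioned samples, and a tile on the X chromosome at 140924251 to 140924500 (13 CpGs) 22.8% ± 4.40 and 12.3% ± 5.13.

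**Figure D2:**
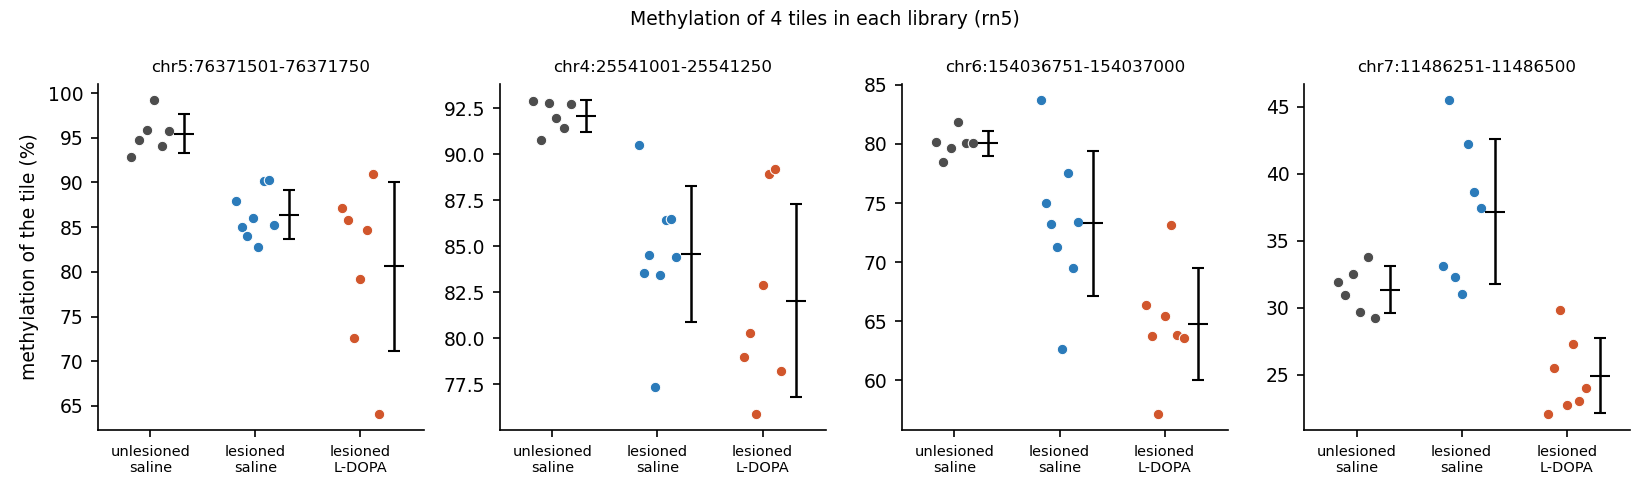
Methylation (%) of 4 tiles in each library of the 3 groups, with mean and SD as bars; the vertical axes differ and do not start at 0. In the chromosome 5 and chromosome 4 tiles, each of the 15 lesioned libraries lies below each of the 6 unlesioned ones.

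No tile passed between L-DOPA and unlesioned saline in the quasi-binomial model or in limma, and 11317 tiles (6.25%, against 6.63% of unchanged tiles in simulated data) and 9366 had an unadjusted p under 0.05. Other splits of the same libraries gave a median of 9179 such tiles in the quasi-binomial model. Of the 11317, 8361 were lower under L-DOPA. Calls appeared when some single L-DOPA libraries were left out. In simulated data this comparison held more wrong calls than the threshold allows, so the adjusted p-values that follow may be too small. Without replicate 1, 2 tiles passed (adjusted p = 0.0363 for both): the chromosome 5 tile at −15.9 points and chromosome 15 at 55973501 to 55973750 at −26.6 points, the latter named after its values were seen. Without replicate 5, the chromosome 4 tile (−11.2 points, adjusted p = 0.0310) and chromosome 7 at 51248501 (−29.1 points, adjusted p = 0.00290) passed. Without replicate 6 the chromosome 4 tile (−11.2 points) and the chromosome 5 tile (−16.5 points) passed (adjusted p = 0.00730 for both), and without replicate 7 the chromosome 5 tile alone (−12.1 points, adjusted p = 0.0331). Over all 21 fits with 1 library left out, the adjusted p of the chromosome 5 tile ran from 0.00730 to 0.498. The smallest adjusted p of any tile in the quasi-binomial model was 0.295 with library series as a term and 0.893 within series 2 alone. Without the 3 libraries with concentrated reads, the chromosome 5 tile passed alone (adjusted p = 0.0145, −10.4 points). The read ratio as a term, also added after the data were seen, gave 139 tiles, all lower under L-DOPA, and 8 with library series as a further term. The model without overdispersion called 13624 tiles with at least 5 points, 11845 of them lower. Without the 3 libraries it called 8849, of which 6427 were lower and 2422 higher.

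The last comparison asks whether tiles moved back towards the unlesioned level under L-DOPA, which would give a negative correlation of the 2 effects. With the lesioned saline libraries split, r averaged 0.104 (SD 0.0794 over 70 splits, range −0.0216 to 0.255) over 139031 tiles. With all 8 lesioned saline libraries in both effects r was −0.280, against −0.460 in simulations without effects, and the covariance was −2.03 against −3.64. Those simulations drew each tile and library independently, so they lack shifts shared by many tiles of a library. The split value was 0.0358 on the logit scale and −0.0195 (SD 0.0527) without the 3 libraries with concentrated reads. No movement back towards the unlesioned level was detected across tiles.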

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

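Of 98 sets of values from one group (5 quantities per library and 28 named tiles, less 1 set in which all values were 0), 6 held a library far from the others of its group, where chance alone gives about 4.9. Lesioned saline replicate 3 had 160192 tested tiles measured, against 170999 for the next library of its group. It also had the lowest total coverage of the 21 libraries, 5.96e+07 reads, and the lowest median reads per tile, 125. At chromosome 13, 113457501 to 113457750, lesioned saline replicate 6 stood at 10.6%, with the next at 8.85%. At chromosome 4, 225132501 to 225132750, L-DOPA replicate 5 stood at 97.4%, with the next at 99.2%. At chromosome 7, 60937751 to 60938000, L-DOPA replicate 3 stood at 98.0% and the rest of its group at 100%. At chromosome 12, 20510751 to 20511000, L-DOPA replicate 5 stood at 88.5%, with the next at 95.2%. At chromosome 14, 80306251 to 80306500, lesioned saline replicate 2 stood at 5.35%, with the next at 3.81%. No explanation was tested for these values.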

How the results depend on the processing

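Tests without the 3 libraries with concentrated reads or with the read ratio as a term were chosen after the data were seen. Tile counts of 0 in the quasi-binomial model stayed 0 in all 3 comparisons under limma on log2 odds, 20 reads per CpG, removal of the highest coverage, scaled coverage, tiles or CpGs in all 21 libraries, no range filter, 1000 bp tiles, autosomes alone, library series as a term and series 2 alone. An adjusted p under 0.01 and the 5-point minimum also gave 0, which was fixed in advance, because both only narrow the calls of the main fit. Unadjusted counts and those of limma stand in the report. Without overdispersion the counts were 7230 for L-DOPA against lesioned saline, 6050 for lesioned against unlesioned saline and 13624 for L-DOPA against unlesioned saline, or 15955, 13548 and 25787 with no minimum difference; in simulated data that model also made 17938 to 21737 wrong calls per comparison. Without the 3 libraries it called 5357, 10744 and 8849 in the same order. The quasi-binomial count was 1 for lesioned against unlesioned saline with only these 2 groups, 1 for L-DOPA against lesioned saline within series 1, and 1 each for lesioned and for L-DOPA against unlesioned saline without the 3 libraries. With the read ratio as a term these last counts were 1 and 139, and with library series added 0 and 8. Leaving out 1 library at a time gave 0 to 2 tiles for L-DOPA against unlesioned saline and 0 to 0 in the other comparisons. Apart from overdispersion, the cause was not tested. Over 591 values of named tiles in other settings and 630 with 1 library left out, 0 changed sign. Little is tested by this. Added terms and other thresholds leave the difference of group means as it is, and the tiles were picked for small p in these same libraries.

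No mean difference passed in any setting run. Within series 2, L-DOPA (n = 4) against lesioned saline (n = 2) could not have passed, because so few libraries allow no exact permutation p under 0.05. L-DOPA minus lesioned saline was 0.557 points without the 3 libraries and −1.04 to −0.157 as single libraries were left out. Lesioned minus unlesioned saline was 0.275 points within series 2 and −0.944 to 0.147 with 1 library left out, above 0 without lesioned saline replicate 2 (0.0912) or unlesioned replicates 3 (0.0957), 5 (0.147) or 6 (0.0976). L-DOPA minus unlesioned saline was −1.68 to −0.340 with 1 left out. The correlation of effects was −0.280 with all lesioned saline libraries in both effects, which by construction lowers it, 0.0358 on the logit scale and −0.0195 without the 3 libraries. Nothing shows that replicate numbers pair the samples: same-numbered libraries had correlations of deviations from −0.456 to 0.298, and 1 of 7, 1 of 6 and 0 of 6 correlated best with their own number. A replicate block called 0 tiles in each comparison and gave mean differences of −0.683, −0.336 and −0.340 points. Promoters in the 3 comparisons, their width, genomic context and gene lists were not run. Unlesioned saline has no library in series 1, so its comparisons have no value there. In simulated data, 0% of 5-point changes, 0% to 2% of 10-point changes and 36% to 48% of 20-point changes were recovered. True changes of such sizes can therefore be missed. The simulation kept the real coverage and dispersion, so the part of each was not tested. All changed tiles had intermediate methylation, so the rates do not cover tiles under 20% or over 80%. For L-DOPA against lesioned saline, the median SE was 2.22 points over all tiles and 4.57 points for tiles of 20% to 80%.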

Other observations

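Of the tests below, those with the read ratio as a term, those without the 3 libraries with concentrated reads, the test of conversion and the spread set beside the library series were chosen after the result was seen. Tiles that separate lesioned from unlesioned samples were few. In 7 of the 139031 common tiles all 15 lesioned libraries lay below all 6 unlesioned ones, and in 2 all lay above, where 2.56 would be had by chance in each direction if libraries were exchangeable. The 7 include, besides the chromosome 5 and chromosome 4 tiles of the report, chromosome 9 at 9454751 to 9455000 (83.9% in lesioned and 91.5% in unlesioned samples on average), chromosome 17 at 14622251 to 14622500 (83.3% and 90.5%) and chromosome 3 at 160855001 to 160855250 (59.7% and 75.7%), named after their values were seen. Of 100 splits of the libraries into 15 and 6, the real one included, 6 gave 7 or more such tiles, and the highest other gave 15, so chance cannot be excluded for the count.

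Some CpGs differed widely between libraries. Of 727193 cytosines with at least 20 reads in all 21 libraries, 6283 (0.864%) had a range of 60 points or more, against a median range of 8.40 points. If a sequence difference at the CpG itself made these, with no linked difference nearby, its neighbour would not follow. For the 3644 with another CpG within 30 bp, the median correlation over the 21 libraries with the nearest one was 0.760. Of these, 73.7% exceeded 0.5, while 12.6% lay under 0.25. This argues against that explanation for most of the 3644, and the rest of the 6283 could not be tested in this way. Variants that act on a whole segment, differences between animals and cell mix stay open, as untested.

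The 3 libraries with concentrated reads (L-DOPA replicates 3 and 7, unlesioned replicate 1) had lower methylation mostly at intermediate tiles. Against the other libraries their medians were −11.4, −13.1 and −10.8 points at tiles of 40% to 60%, and −1.04, −0.795 and −1.24 points at tiles of 90% to 99%, at most 0.115 times the former, which argues against conversion of methylated cytosines, whose loss would grow with the level. At an equal 8 to 14 CpGs, low-methylated tiles took 4.10 to 5.08 times the reads of high-methylated tiles in these libraries and 1.54 to 3.23 times in the other 18. A ratio above the others was the outcome set for more reads kept from unmethylated copies in library preparation. It was also the outcome set against another cell mix alone. The test cannot decide between these, because the libraries were picked for excess reads in CpG-dense tiles, which are low-methylated. Other properties of tiles with equal CpG number were not matched. For L-DOPA against lesioned saline, 83.3% of the calls made without overdispersion were lower, and 23.6% without the 3 libraries, under the 35% to 65% set for a bias made by them alone, while other splits of the same libraries gave 3.38% to 95.7%, so a share of 83.3% lies within what other groupings give. Lesioned saline replicate 2 had an intermediate value of −7.22 points at tiles of 40% to 60%.

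The 139 tiles lower under L-DOPA than in unlesioned samples with the read ratio as a term had a median difference of −14.3 points, and lesioned saline was lower than unlesioned in 97.1% of them, by a median of −7.48 points. A loss that begins with the lesion may underlie them, as a hypothesis, but the unlesioned libraries are shared by both differences. Lesioned saline of series 1 (n = 6) and series 2 (n = 2) differed there by a median of −0.685 points (SD 4.69 over tiles), far from −14.3, which argues against the library series as the whole cause, although only 8 tiles were called with library series as a further term. Within series 2 alone, the median difference from unlesioned samples was −14.8 points for L-DOPA (100% of tiles below 0). For lesioned saline it was −5.80 points (95.7% below 0). The tiles were picked with these same libraries, which favours such values. When tiles were picked with 3 unlesioned libraries, lesioned saline differed from the other 3 by −1.28 points on average (SD 1.34, range −4.10 to 1.72, 19 of 20 overlapping choices below 0) beyond tiles of the same level. The value depended on unlesioned replicate 1, whose reads are concentrated: −4.10 to −0.117 where it was used to pick, and −1.47 to 1.72 where it was not. The average lay between the bounds set for and against, so chance values of the unlesioned libraries stay open. Of 60 splits, 3 gave as many tiles (highest other 2711), so chance cannot be excluded.

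Chance cannot be excluded for the counts above 0 below, given as splits with a result as large, the real one included, for L-DOPA against lesioned saline, lesioned against unlesioned saline and L-DOPA against unlesioned saline in turn. With the read ratio as a term, 9 and 3 of 60 splits gave as many as the 1 and 139 tiles of the last 2 comparisons (highest other 675 and 2711). Without overdispersion, 63, 68 and 36 of 100 splits gave as many as 7230, 6050 and 13624 tiles (highest other 23094, 24471 and 36574). At an unadjusted p under 0.05, 79, 72 and 33 of 100 gave as many as 6937, 6194 and 11317 (highest other 19464, 20735 and 35979). Runs of at least 3 neighbouring tiles with such a p and one direction numbered 3, 2 and 9, and 69, 73 and 29 of 100 splits gave as many (highest other 42, 57 and 180). A count of 0 is reached by any split, so all 100 splits of the quasi-binomial counts (highest other 1, 15 and 9433) and all 60 for L-DOPA against lesioned saline with the read ratio as a term (highest other 0) test nothing. Splits with several times the real count point to a structure of the libraries other than the groups.

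No relation of the read ratio and mean methylation was detected in the other 18 libraries (r = −0.0530, permutation p = 0.834; r = −0.375 without the 2 farthest ratios). Within series 1 of these (n = 8) r was −0.691 (permutation p = 0.0528) and rho −0.786 (permutation p = 0.0287), and within series 2 (n = 10) r was 0.385 (permutation p = 0.281) and rho 0.309 (permutation p = 0.389). The second principal component of tile methylation (9.87% of the variance) was carried by unlesioned replicate 4 (loading 0.833, the other libraries −0.277 to 0.135), which had the lowest read ratio, 13.7.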
